A study of Mus musculus with 5 samples.

How the data were processed

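The series measured Nr1d1 binding by ChIP-seq in mouse Th1 cells in 5 libraries, which the sample titles place in 3 groups: 3 Nr1d1 ChIP libraries (a, b and c), 1 IgG mock and 1 input DNA. The antibody label names the Nr1d1 antibody for all 5 libraries, the mock and the input included, so groups were taken from the titles. Per the labels' protocols, chromatin was crosslinked with formaldehyde and sonicated before the pull-down. Reads were aligned to mm10 (GRCm38), and BWA and HOMER were used, per the submitters' processing notes, which give no version. The peak caller and the way the 3 ChIP libraries were combined are not given in the sources used here.

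The authors deposited peak lists over the input for the ChIP and for the IgG mock, a list without overlap, and a HOMER annotation of each. The q-value of a peak is deposited as an FDR printed to 6 decimals, and all values lay under 0.05. The score in the HOMER tables deposited by the authors was equal to the peak's length in bp for every annotated peak. Peak lengths were multiples of 25 bp. The annotation gives the nearest gene, the distance to its TSS and a class (promoter-TSS, exon, intron, TTS or intergenic). Peaks have no read count, height or fold, so the depth behind a peak is unknown and intervals cover counting of peaks only. A check of the list without overlap found that all 14471 of its intervals were ChIP peaks and that it held each of the 14471 ChIP peaks without an IgG overlap of 1 bp or more. It was used as the ChIP-specific list. Of these peaks 2, and 1 IgG peak, had no annotation and were left out of tests on classes and genes.

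All choices of lists, tests and alternatives were made before the data were examined, except those named below. A preference for fold enrichment had been set, but as the lists held none, peaks were ordered by FDR and, for ties, by length, and strongest means first in this order. The shared fraction was tested by moving IgG peaks at random within their chromosomes 1000 times (bedtools 2.31.1 for the moves, own code for overlaps in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1). Moved peaks could fall in assembly gaps, where no peak is called. Medians were compared by 100000 permutations, and shares by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 5 classes, 21 chromosomes or 17 gene lists. Intervals of shares are Wilson intervals at 95%.

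The 17 lists held genes of the core clock, the NCoR-HDAC3 corepressor, lipid and liver metabolism, Th1, Th2, Th17 and regulatory T cells, T cell receptor signalling, glycolysis, interferon response, myeloid cells, B cells, NK and CD8 cells, hepatocytes, long neuronal genes, olfactory receptors and ribosomal proteins. A gene counted when it was the nearest gene of a peak, with genes nearest to any ChIP or IgG peak as the background. Gene coordinates and older symbols came from the RefSeq annotation of GRCm38.p6, the build of the files, and 77.8% of ChIP-specific peaks had a gene found there. Replacing older symbols was decided after the first counts had been seen. Each list was also compared with 10000 random lists of protein-coding genes, each gene being replaced by one with surroundings of similar size. Replacements were drawn one by one from all chromosomes. Members that lie close together were thus treated as independent, and for lists with such members the ranges may be too narrow. Surroundings are the gene body and the gaps up to the midpoint to the nearest RefSeq gene on each side. Peaks were assigned by the nearest TSS in the authors' annotation, so the matching covers that assignment only in part. The same matching was used for peaks in gene bodies. In the matched comparison 21887 genes formed the background, and list sizes are those of protein-coding members. The exact McNemar tests, the shares of predicted genes and the counts of peaks in gene bodies were also added later.

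Named genes followed a rule: the 10 strongest ChIP-specific peaks within 100 kb of a gene, the 10 strongest at promoters, up to 4 members per list with the peak nearest to the TSS, 11 clock and Th1 genes in every case, and the 5 strongest IgG peaks. Some genes that the rule names are not reported here. Other names were chosen after values were seen and are marked so. The alternatives changed the minimum overlap, the FDR threshold, the chromosomes kept, the promoter definition, the comparison set and the gene assignment. Motif searches with 12 consensus sequences, among them the RORE and RevDR2 sites, needed a genome sequence, which was not used here, and repeat annotation was not used here either. With lists for each antibody as a whole, no replicate could be left out.

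The tests were tried on simulated data. With 10% of peaks copied into the other list, relocation called 20 of 20 simulated lists, and 1 of 20 without copies. Fisher's test called 193 of 200 simulated class differences of 1 percentage point and 10 of 200 without a difference. The permutation of medians called 33 of 40 lists whose distances were scaled by 0.9 and 0 of 40 unscaled ones. Matched lists of 60 genes were called in 190 of 200 cases when genes with a peak had a weight of 3, and in 2 of 200 at equal weight. These calls used an unadjusted p under 0.05. All fixed lists except ribosomal proteins and olfactory receptors held fewer than 60 genes and were judged after adjustment. For those lists, the clock and T cell lists included, the power was not simulated and would be lower.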

Results

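Chromatin binding of Nr1d1 (REV-ERBα), a heme-binding nuclear receptor that acts as a transcriptional repressor in the circadian clock, was measured by ChIP-seq in mouse Th1 cells. The cells were naive CD4 T cells of wild-type C57BL/6 mice that had been activated through CD3 and CD28 and differentiated in culture with IL-12, IFNγ and an antibody against IL-4. The series held 5 libraries: 3 Nr1d1 ChIP libraries, 1 mock pull-down with IgG and 1 input DNA library. The deposited lists covered each antibody as a whole, with 19586 peaks for the Nr1d1 ChIP and 17111 for the IgG mock, both over the input. A further list held the 14471 ChIP peaks that lay apart from the IgG peaks, called ChIP-specific here. No value was given per library, so the 3 ChIP libraries could not be compared with one another, and the read depth was unknown. All p-values below were therefore computed over peaks or genes and compare these lists, not populations of cells or mice.

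The first comparison asked how far the Nr1d1 ChIP peaks differed from the background seen with IgG. The strongest peaks of both lists lay at shared sites. Of the 19586 ChIP peaks, 5115 (26.1%, Wilson 95% interval 25.5 to 26.7) overlapped an IgG peak by at least 1 bp, against a mean of 0.289% and at most 0.419% when IgG peaks were placed at random within their chromosomes. This was 90.3 times the random mean (one-sided permutation of positions, p = 0.001, the smallest that 1000 relocations can give). Both lists were called over the same 1 input library, so part of this excess may come from that shared control. Relocation removes every shared cause at once and gives only the chance level, so the part due to the input is unknown. Ordered by FDR and then by length, the first IgG peak overlapped an exon of Sox11, a developmental transcription factor, 562 bp from the TSS (chromosome 12, 27341276 to 27342749, mm10), and the next lay in an intron of Qpct (chromosome 17, 79087301 to 79088599). The other IgG peaks among the first 5 were nearest to Gm8579, Yam1 and Nrg3, a ligand of the ErbB4 receptor.

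The overlap was graded by peak strength. In the decile of ChIP peaks with the lowest FDR, 89.3% (87.8 to 90.6) overlapped an IgG peak, in the next decile 53.4%, and in the weakest decile 7.66%. Of the 1762 ChIP peaks with an FDR printed as 0, 1600 (90.8%, 89.4 to 92.1) overlapped an IgG peak, and 162 were ChIP-specific. The IgG list had a similar gradient, from 84.8% (83.0 to 86.4) in its strongest decile to 14.4% in its weakest. An FDR printed as 0 was shared by 2934 IgG peaks, more than the 1712 of the strongest decile. The first IgG decile was therefore set apart from the rest of these by length only. Of the 2934, 2197 (74.9%, 73.3 to 76.4) overlapped a ChIP peak. ChIP peaks over an IgG peak had a median FDR of 0.00595 and a median length of 300 bp, against 0.0146 and 200 bp for ChIP-specific peaks. The difference in median FDR was -0.00865 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give).

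**Figure D1:**
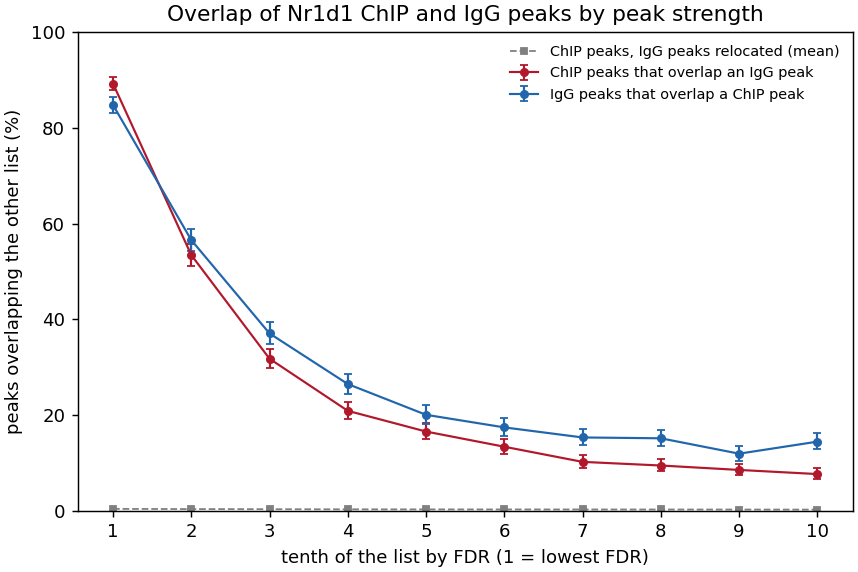
Percent of peaks that overlap the other list (y axis) in deciles of each list ordered by FDR (x axis, 1 is the lowest FDR), for Nr1d1 ChIP peaks in red and IgG peaks in blue, with Wilson 95% intervals. Ties in FDR were ordered by length. Grey squares give the mean for ChIP peaks with IgG peaks relocated at random. The ChIP curve falls from 89.3% to 7.66%, while the relocated level stays below 1%.

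Of the 162 ChIP-specific peaks with an FDR printed as 0, the 10 longest within 100 kb of a gene, 1 per gene, included peaks at 2 genes of neuronal proteins. Crmp1, a cytosolic phosphoprotein of growing axons, had a peak over an exon at its start (chromosome 5, 37242001 to 37242499, 170 bp downstream of the TSS). Dner, a neuronal transmembrane protein with EGF repeats, had a promoter peak (chromosome 1, 84696401 to 84696874, 416 bp upstream of the TSS). The peak nearest to Tex29 was intergenic (chromosome 8, 11885276 to 11885799, 43476 bp from the TSS). The remaining 7 peaks were assigned to the predicted genes Gm22120, Gm26024, Gm25724, Gm12479, Gm28386, Gm13197 and Gm26089, and the peak near Gm22120 was the longest of them at 800 bp (chromosome 12, 105882626 to 105883424). Predicted genes of this kind were nearest to 47.5% (39.5 to 55.7) of ChIP-specific peaks with an FDR printed as 0 and 38.2% (37.3 to 39.1) of all ChIP-specific peaks within 100 kb of a gene.

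In the same order, the first 10 ChIP-specific promoter peaks included no gene of the T cell or clock lists. Besides Dner, they lay at Lrrc49, at Serpine2, a secreted serine protease inhibitor (chromosome 1, 79858451 to 79858749, 35 bp downstream of the TSS), at Mapkapk5, a kinase downstream of MAP kinases (chromosome 5, 121534451 to 121534749, 120 bp upstream), and at Hoxa13, a homeobox factor of limb and genital development (chromosome 6, 52260876 to 52261149, 132 bp upstream). The others were at the noncoding or predicted genes Gm11672, Gm24270, Gm16064, Gm11431 and A530058N18Rik. The last of these had an FDR of 0.00104, and the others an FDR printed as 0.

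The next comparison asked whether ChIP-specific peaks lay in other parts of the genome than IgG peaks. Promoters held 799 of 14469 annotated ChIP-specific peaks (5.52%, 5.16 to 5.91) and 935 of 17110 IgG peaks (5.46%, 5.13 to 5.82), a difference of 0.0575 percentage points (95% interval -0.445 to 0.564; Fisher's exact test, p = 0.824). Introns held 30.8% of ChIP-specific and 29.0% of IgG peaks, and intergenic regions 57.2% and 59.7%. These were differences of 1.74 and -2.48 percentage points (Fisher's exact test, Benjamini-Hochberg adjusted over 5 classes, p = 0.00197 and 4.11e-05). Exons (4.52% against 4.11%) and transcription termination sites (1.97% against 1.69%) did not differ past the threshold (Fisher's exact test, adjusted p = 0.0934 for both). Against the 11990 annotated IgG peaks that overlapped no ChIP peak, of which 3.98% were at promoters, the promoter share was higher by 1.54 points (1.03 to 2.05; Fisher's exact test, p = 4.59e-09). Against the 5115 ChIP peaks over IgG peaks, of which 8.78% were at promoters, the difference was -3.26 points (-4.14 to -2.42; Fisher's exact test, p = 2.21e-15).

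ChIP-specific peaks lay nearer to genes than IgG peaks, at a median of 30846 bp from a TSS against 34550 bp. The difference was -3704 bp (two-sided permutation test, p = 1e-05, the smallest possible). For ChIP peaks over IgG peaks the median was 24942 bp. Bodies of protein-coding genes held 38.3% (37.5 to 39.1) of ChIP-specific peaks, against 38.2% when the peaks were placed at random (two-sided permutation of positions, p = 0.937). IgG peaks were in gene bodies less often than random placement gave, at 36.3% against 38.1% (two-sided permutation of positions, p = 0.002, the smallest that 1000 relocations can give). Placement could fall in assembly gaps, so both random shares may be too low, and a small deficit of ChIP-specific peaks in gene bodies is not excluded.

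Chromosome X was dense in peaks of both kinds. It held 8.71 ChIP-specific and 11.1 IgG peaks per Mb, against 5.20 and 6.11 per Mb over the autosomes, whose ChIP-specific density ran from 3.42 to 7.38 per Mb. The share of peaks on X was 10.3% in the ChIP-specific and 11.02% in the IgG list, a difference of -0.753 points (Fisher's exact test, p = 0.031, adjusted p = 0.325). None of the 21 chromosomes passed Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05, X and chromosome 2. On chromosome 2 the shares were 4.30% and 3.63% (Fisher's exact test, adjusted p = 0.0528).

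The study set out to map where Nr1d1 binds in Th1 cells, so genes of the clock and of Th1 identity were examined with their positions. Among 11 such genes named in advance, 2 were nearest to a ChIP-specific peak. Over all 21887 protein-coding genes, 3829 (17.5%) were. Cry1, a core repressor of the clock, had an intergenic peak 6021 bp upstream of its TSS (chromosome 10, 85190976 to 85191174, FDR 0.0088), and an IgG peak that was assigned to Mterf2 lay inside the gene (85143976 to 85144099, FDR 0.00845). Ifng, the signature cytokine of Th1 cells, was nearest to an intergenic peak that lay 169578 bp downstream of its TSS (chromosome 10, 118610501 to 118610749, FDR 0.00595). Nr1d1 and Arntl, the BMAL1 gene, were each nearest to an IgG peak and to no ChIP peak. The IgG peak at Nr1d1 was 525 bp long, had an FDR printed as 0 and lay at a transcription termination site (chromosome 11, 98769501 to 98770024), while the nearest ChIP peak was 779508 bp from the gene. The IgG peak at Arntl was intronic (chromosome 7, 113249726 to 113249849). Clock was assigned no peak, although a ChIP-specific peak lay inside the gene (chromosome 5, 76304801 to 76305074, FDR 0.0261) and was annotated as the promoter of Gm7467. That peak was 529 bp from the higher coordinate of Clock and 94933 bp from the lower. Strand was not considered, so the higher coordinate may be the start of transcription and the peak may lie at the start of Clock. No ChIP or IgG peak was assigned to Tbx21, the gene of the Th1 factor T-bet, or to Stat4, Il12rb2, Nr1d2, Nfil3 or Npas2.

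Of the 22 core clock genes, 5 were nearest to a ChIP-specific peak and 5 to an IgG peak. Cry2 had an exonic peak 124 bp downstream of its TSS (chromosome 2, 92433776 to 92434049, FDR 0.0275), and Bhlhe40, a clock-controlled repressor, a promoter peak (chromosome 6, 108659726 to 108659949, FDR 0.0183). Csnk1e, a kinase of the period proteins, had an intronic peak (chromosome 15, 79437351 to 79437599, FDR 0.0088), and Rorb, chosen here after its values were seen, had 5 intronic ChIP-specific peaks and 4 IgG peaks. Random lists of genes with surroundings of the same size contained 4.57 genes with a ChIP-specific peak on average (95% range 1 to 8; permutation p = 1.00). Among 9 genes of the NCoR-HDAC3 corepressor, through which Nr1d1 represses transcription, those with a ChIP-specific peak included Tbl1xr1 and Hdac2, and Tbl1xr1 had IgG peaks too.

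The numbers of T helper genes with a ChIP-specific peak lay within the 95% range of matched random lists for each of the Th1, Th2, Th17 and regulatory T cell lists. Of 28 Th1 genes, 4 had a ChIP-specific peak and 0 had an IgG peak, while matched random lists held 3.59 on average for either kind. Besides Ifng, these were Eomes, a T-box factor, with a peak in an exon 189 bp downstream of the TSS (chromosome 9, 118478926 to 118479174, FDR 0.00956), the chemokine receptor gene Cxcr3 (X, 101724651 to 101724749, intergenic, FDR 0.0367) and Havcr2, which encodes the inhibitory receptor TIM-3 (chromosome 11, 46465001 to 46465274, intron, FDR 0.0088). The 0 Th1 genes with an IgG peak lay below the range of 1 to 7 in matched lists (permutation p = 0.0434, adjusted p = 0.148). Counted by peaks, 4 ChIP-specific against 0 IgG peaks did not pass adjustment (Fisher's exact test, p = 0.0441, adjusted p = 0.428). With peaks in the gene body or within 5 kb, 2 Th1 genes had a ChIP-specific peak against 3.39 in matched lists, and 0 had an IgG peak, within the range of 0 to 7 (permutation p = 0.0576). Of 13 Th2 genes, Il5 (chromosome 11, 53721901 to 53722149, intron) and Maf had ChIP-specific peaks. Of 14 Th17 genes, Il17f (chromosome 1, 20778851 to 20778974, intron) and Il17a (chromosome 1, 20713276 to 20713549, intergenic) did, and of 14 regulatory T cell genes Tgfb1 did (chromosome 7, 25688201 to 25688324, promoter). Of 30 genes of T cell receptor signalling, 2 had a ChIP-specific peak, among them Cblb with an intronic one, against 6.26 genes in matched lists (permutation p = 0.0582, adjusted p = 0.277).

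Lists of metabolism and of other cell types had about as many ChIP-specific as IgG genes. Of 21 genes of lipid and liver metabolism, 5 had a ChIP-specific and 5 an IgG peak. The former included Elovl5, a fatty acid elongase with an intronic peak 191 bp from its TSS (chromosome 9, 77917476 to 77917774), Ppargc1a, Pck1 and Lpl. Of 19 glycolysis genes, 3 had a ChIP-specific peak, among them promoter peaks of the glucose transporter gene Slc2a3 (chromosome 6, 122801601 to 122801774) and of Mtor (chromosome 4, 148448601 to 148448824), and 3 had an IgG peak. Ifi44 was the interferon-stimulated gene with a ChIP-specific peak, of 16. Of 15 myeloid genes, Cebpa, Tlr4 and Adgre1 had both a ChIP-specific and an IgG peak. Of 12 B cell genes, 0 had a ChIP-specific peak and 1 had IgG peaks, Pax5 (named after its values were seen), and NK and CD8 genes had 0 of 10 in either list. Of 13 hepatocyte genes, 5 had a ChIP-specific peak, with Serpina1a, Apob, F9 and Cyp3a11 the nearest, against 1.87 in matched lists (permutation p = 0.056, adjusted p = 0.277), and 6 had an IgG peak, against 1.64 (permutation, adjusted p = 0.0476). With peaks in the gene body or within 5 kb, the IgG call was lost, at 4 against 1.47 (permutation, adjusted p = 0.514), and the ChIP-specific number was 2 against 1.62 (permutation p = 1.00). Of 81 ribosomal protein genes, 9 had a ChIP-specific and 6 an IgG peak, and the ChIP-specific peaks nearest to a TSS were at Rpl34, Rps6, Rps4l and Rps27.

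Among the 12186 genes nearest to any peak, 2 of the 17 lists passed the test against other genes, and neither held a gene of T cell function or of the clock. All 16 long neuronal genes with large introns, such as Csmd1, Magi2 and Dmd, had a ChIP-specific peak, against 66.4% of other genes (Fisher's exact test, adjusted p = 0.0194), and all 16 also had an IgG peak. Olfactory receptor genes had one less often, 83 of 186 (44.6%) against 66.8% of other genes (odds ratio 0.401; Fisher's exact test, adjusted p = 1.52e-08), while 119 had an IgG peak. The other lists had an adjusted p of 1.00 in the same Fisher's exact test. Few of their genes were nearest to any peak: 9 of the core clock, 4 of Th1, 4 of Th17 and 2 of T cell receptor signalling. All 4 Th1 genes had a ChIP-specific peak, and this still gave p = 0.308 (Fisher's exact test). A list of that size could not pass for enrichment, so this test does not speak on T cell genes. Olfactory receptor genes with ChIP-specific peaks near the TSS included Olfr251, Olfr599, Olfr284 and Olfr26. Against random lists matched on the size of the gene surroundings, 0 of the 17 lists passed for ChIP-specific peaks and 1 had an unadjusted p under 0.05. There the long neuronal genes numbered 16 against 12.2 (permutation p = 0.0264, adjusted p = 0.277) and the olfactory receptors 82 against 93.9 (permutation p = 0.206, adjusted p = 0.701). With peaks in the gene body or within 5 kb, the olfactory receptors passed, with 56 genes against 93.1 (permutation, adjusted p = 0.0034). An IgG peak was there in 79, against 87.3 (permutation p = 0.385). Random genes were matched on surroundings and not on gene length, so this test cannot tell fewer peaks from shorter genes. It also treats receptors that lie close together as independent, so its p-value may be too small. The direct comparison of olfactory receptors with a ChIP-specific peak alone (66) and an IgG peak alone (102) did not pass adjustment (exact McNemar test, p = 0.00675, adjusted p = 0.236 over 35 gene groups), nor did that in gene bodies or within 5 kb, 48 against 71 (exact McNemar test, adjusted p = 0.757). Counted by peaks, the direction for the long neuronal genes turned, with 105 ChIP-specific peaks (0.726%) and 157 IgG peaks (0.918%; Fisher's exact test, odds ratio 0.789, p = 0.062, adjusted p = 0.428).

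**Figure D2:**
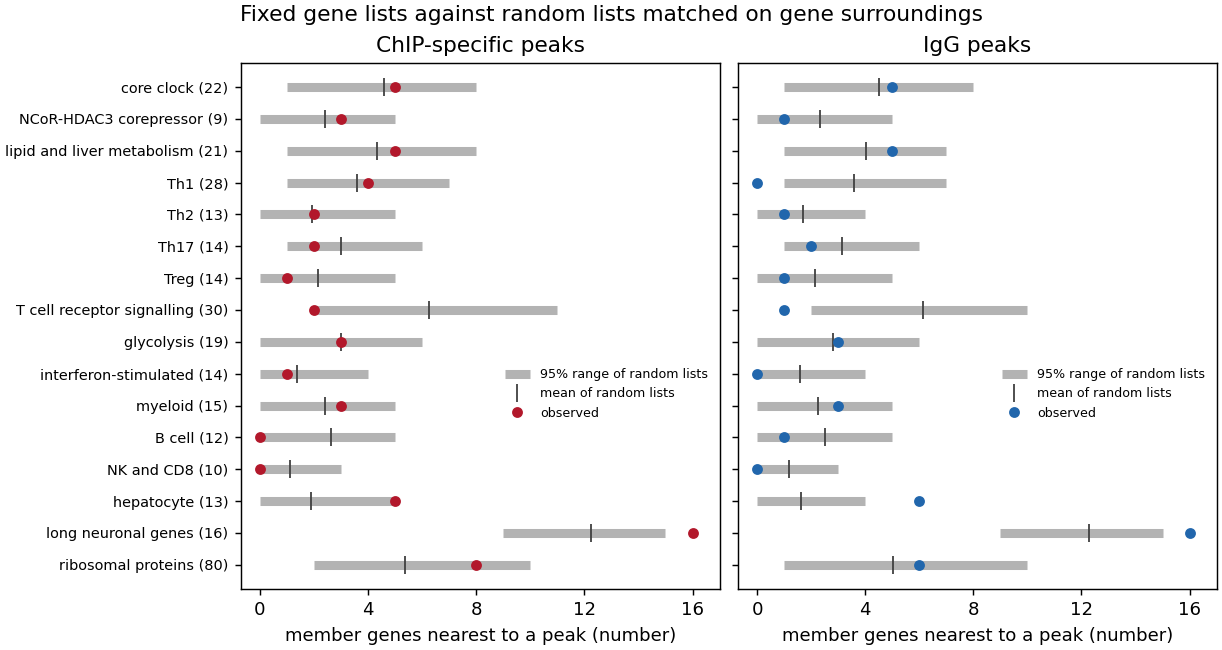
Number of member genes nearest to a ChIP-specific peak (left) or an IgG peak (right) for the fixed lists other than olfactory receptors, with the protein-coding members of each list in parentheses. Points are observed numbers, ticks the mean and grey bars the 95% range of 10000 random lists matched on the size of the gene surroundings; the 22 core clock genes stood at 5 in both panels, and the Th1 genes at 4 and 0.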

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

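Several alternatives were chosen after the results were seen: the shift of IgG peaks by 20 to 500 kb, ChIP peaks over IgG peaks as a comparison set for promoters, both alternatives for X, counts of peaks in place of genes, peaks in gene bodies, symbols as the authors give them, the background without shared IgG peaks, and the other counts of the 11 clock and Th1 genes. The overlap share stayed far above relocation in every alternative run, from 22.5% with an overlap of 50% of each peak to 33.5% in the upper 50% of each list by FDR. The distances to TSS, the FDR difference and the list without overlap kept their direction and call in all alternatives run. The promoter share, 0.0575 points above IgG, depended on the definition: it was 1.07 points within 5 kb of a TSS, 1.54 against IgG peaks without a ChIP peak, -0.759 in the upper 50% by FDR and -3.26 against ChIP peaks over IgG peaks. The share on X passed the threshold against IgG peaks without a ChIP peak, at -1.21 points (Fisher's exact test, adjusted p = 0.0165), where 2 chromosomes were called. In the upper 50% by FDR it did not pass, at -1.39 points (Fisher's exact test, adjusted p = 0.0664). Of the 17 gene lists, 2 passed in the comparison with other genes, 1 with peaks within 10 kb of the TSS, 1 in the upper 50% by FDR, 1 (olfactory receptors) with peaks in the gene body or within 5 kb against matched lists, 0 against random lists matched on domain size, 0 with peaks in place of genes, and 0 with symbols as the authors give them and peaks within 10 kb. For the long neuronal genes within 10 kb, the difference turned to -7.08 points (-7.07 with the authors' symbols), neither past the threshold. Of the 11 clock and Th1 genes, 1 in place of 2 had a ChIP-specific peak within 100 kb of the TSS, and 1 had one in the gene body. The causes were not tested. Motif alternatives and those removing repeats were not run. No paired analysis was possible because the lists are not per library, and for the same reason no replicate was left out. Unknown depth limits any statement on peaks that are missing.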

Other observations

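The gene families in the next paragraph, and the tests of IgG peaks at strong sites, of small surroundings, of a low yield at T cell genes, of the antibody on X and of windows along X, were chosen only after the results were seen.

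A set of homeobox genes of embryonic patterning, without the Hox genes, stood out in both lists. Of 61 Dlx, Irx, Msx, Nkx, Otx, Pax and related genes, 26 were nearest to a ChIP-specific peak, against 9.43 in lists with surroundings of the same size, a ratio of 2.76 (permutation, adjusted p = 0.0034 over 17 families). With IgG it was 25 genes against 8.89 (permutation, adjusted p = 0.0017), and 19 genes had both, among them Pax6, Otx2, Nkx2-1 and Msx1. The 39 Hox genes, tested as another family, did not stand out by the same assignment. They numbered 3 against 2.53 for ChIP-specific peaks (permutation p = 0.94) and 4 against 2.52 for IgG peaks (permutation, adjusted p = 0.635). Counted in the gene body or within 5 kb, Hox genes numbered 4 against 2.88 for ChIP-specific peaks (permutation p = 0.643). For IgG peaks they numbered 7 against 2.64 there (permutation, adjusted p = 0.0675). For ChIP peaks over IgG peaks they passed, with 6 against 1.33 (permutation, adjusted p = 0.0391). Cytochrome P450 genes were nearest to IgG peaks in 27 of 92 cases, against 12.99 (permutation, adjusted p = 0.0017), and to ChIP-specific peaks in 23 against 14.2 (permutation, adjusted p = 0.117). Random genes were drawn one by one. Where family members lie close together, as Irx1, Irx2 and Irx4 do on chromosome 13, the permutation p-values of this paragraph may be too small. Glutamate receptor genes, such as Gria1, Grik2 and Grm5, had a ChIP-specific peak in 19 of 26 cases, against 12.4 (permutation, adjusted p = 0.0374), and an IgG peak in 14. There 5 genes had a ChIP-specific peak alone and 0 an IgG peak alone, too few for an exact McNemar test to reach the threshold. With peaks in the gene body or within 5 kb the family no longer passed for ChIP-specific peaks (18 against 13.5, permutation, adjusted p = 0.155) and passed for IgG peaks (19 against 13.7, permutation, adjusted p = 0.0442). Of 64 genes of interleukins and their receptors, 1 had an IgG peak in the gene body or within 5 kb, against 8.20 in matched lists (permutation, adjusted p = 0.0159), and 9 had a ChIP-specific peak, against 8.55 (permutation p = 0.972). The direct comparison, 9 with a ChIP-specific peak alone and 1 with an IgG peak alone, did not pass adjustment (exact McNemar test, p = 0.0215, adjusted p = 0.752 over 35 gene groups). By the nearest TSS, 5 had an IgG peak, against 8.96 (permutation, adjusted p = 0.298). Sox genes also passed for IgG peaks in the gene body or within 5 kb, with 9 of 19 against 3.40 (permutation, adjusted p = 0.0085). For ChIP-specific peaks they numbered 6 against 3.49 there (permutation, adjusted p = 0.2935), and by the nearest TSS 7 against 3.47 for IgG peaks (permutation, adjusted p = 0.1445).

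The strongest ChIP peaks overlapped IgG peaks most often, in 89.3% of the decile with the lowest FDR. Chance overlap of longer peaks is too rare to account for it, since random placement covered at most 0.919% of this decile. That these sites are enriched over input in any pull-down stays open: 84.8% of the strongest decile of IgG peaks overlapped a ChIP peak, but this is the same overlap seen from the other list. That the IgG library holds an Nr1d1 pull-down by mislabelling stays open: 3 core clock genes had a shared peak and matched lists gave 0 to 5, a range that starts at 0, so no number could have spoken against it. Low coverage of the 1 shared input, which would give peaks in both lists, and the Nr1d1 antibody itself were not tested, since the lists give no reads per library.

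Genes of T helper cells and of T cell receptor signalling were rarely the nearest gene of an IgG peak, in 5 of 96 cases against 16.6 in matched lists, and for ChIP-specific peaks numbered 11 against 16.7 (permutation p = 0.123). For IgG peaks, matching on surroundings did not remove the pattern: the number was 0.302 times that of matched lists (permutation p = 0.001, unadjusted). The test was chosen after the counts were seen and uses those counts. None of the 5 lists alone passed adjustment, the lowest being T cell receptor signalling (permutation, adjusted p = 0.0714). Single lists hold fewer genes, so this does not bear on surroundings. The matching covers assignment by the nearest TSS only in part, so small surroundings are not excluded. For ChIP-specific peaks small surroundings stay open, since 11 lies inside the range of 10 to 24. A low yield at genes used in these cells in any pull-down against input stays open too, since the 5 genes of the IgG list are the pattern itself, and all ChIP peaks, with 13 genes, lay below the range of 14 to 29 by the nearest TSS (permutation p = 0.0332) but with 16 inside that of 14 to 28 in gene bodies or within 5 kb (permutation p = 0.261). A role of the Nr1d1 antibody cannot be told apart from none, as the odds ratio of peaks at these genes was 1.104 (Fisher's exact test, p = 0.853) and by genes 9 had a ChIP-specific peak alone and 3 an IgG peak alone (exact McNemar test, p = 0.146; 12 and 5 in gene bodies or within 5 kb, p = 0.143).

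Chromosome X held more peaks per Mb than the autosomes. Gene-poor sequence does not account for it, as windows of 1 Mb on X held 1.55 times (1.42 to 1.69) the ChIP-specific peaks of autosomal windows with as many protein-coding genes. Whether the Nr1d1 antibody was the cause cannot be told from the share of peaks on X. The difference in share was -0.753 points in the ChIP-specific against the IgG list (Fisher's exact test, p = 0.031, adjusted p = 0.325 over 21 chromosomes). It did not pass adjustment, and shared peaks were removed from the ChIP-specific list only. The IgG list had the excess too, with 11.1 peaks per Mb on X against 6.11 over the autosomes. That the pull-downs held more X copies than the input stays open as a hypothesis: 94.1% (73.0 to 99.0) of the 17 windows of 10 Mb on X lay above the median autosomal window, but any cause that acts along the whole chromosome would give this. Mappability and repeats on X were not tested.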
